A study of Mus musculus with 12 samples.

How the data were processed

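The FPKM values were computed by the authors and used as deposited. Per the submitters' processing notes, reads were checked with FastQC 0.11.2 and aligned to mm10 with Bowtie, whose version is not given in the sources used here. The program that counted reads, the gene annotation it used, read length, trimming and strand handling are not given in the sources used here. Reads themselves were not used here. The values fitted FPKM: with the gene lengths of GENCODE vM21 on GRCm38 (mm10), 98.7% of them were within 0.1 of a whole number of reads at 1 depth per library. The build of the annotation can differ from the one the authors used, and 715 identifiers without a symbol carry no position here. Mitochondrially encoded genes were absent from the files, so their share was not analysed here.

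The comparisons, the filter, the gene lists, the rule for naming genes and most of the alternatives were chosen before the data were examined. FPKM were transformed to log2 after a pseudocount of 1. Genes with a mean of at least 1 FPKM in at least 1 group were kept, which left 13511. A model with 1 mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with a trend of variance on abundance and robust moderation. The 5 pairwise comparisons and the interaction were contrasts of that model. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and a gene was called below 0.05. Fold changes are differences of log2(FPKM + 1), and a fold given as lower is the reciprocal.

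For each list of genes, members were counted as higher, lower or not passed, with p-values adjusted over all genes and again over the list alone. Lists were tested as groups with limma's camera, once with its preset correlation of 0.01 and once with a correlation estimated from the data, and with fry. Camera sets a list against the other genes and fry tests it against no change, and a list is called where camera passes. The lists were Th17 lineage, Th1 lineage, Th2 lineage, Treg, Tfh, T helper cytokines, AhR targets, naive and quiescent T, T cell activation, glycolysis and hypoxia, cholesterol synthesis, fatty acid synthesis, cell cycle, type I interferon response, ATF4 and amino acid response, ER unfolded protein response, NRF2 oxidative stress, heat shock, circadian clock, oxidative phosphorylation, and apoptosis and p53. Lists of markers of other cells covered B, CD8 T and NK, gamma delta T, myeloid, erythroid and platelet, and stromal cells. Of these 27 lists, 24 had at least 5 measured members and were tested. The lists were written from general knowledge of the genes, and none came from these data.

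Genes were named by rule. Il17a, Il17f, Il22, Il23r, Ccr6, Il10, Foxp3, Ifng, Ahr and Cyp1a1 were named in the comparisons with vehicle and of both compounds with GSK805. Each comparison added the 6 largest rises and 6 largest falls among called genes that had groups without overlap and a mean of at least 5 FPKM in a group. Unnamed, ribosomal protein, mitochondrial and receptor segment genes and pseudogenes were left out. Up to 3 members of each of up to 6 lists with the most passing members were added. For the interaction the overlap condition was dropped. A few genes that met the rule are not reported here, though they stay in the fits and list counts.

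Sharing between comparisons was measured across genes by Pearson and Spearman correlation and by the overlap of calls. The overlap by chance was the product of the marginal fractions. For the pair with shared vehicle libraries, 100 draws simulated groups without any change on the same controls. Library measures were compared with exact permutation tests, two-sided, where 3 against 3 libraries give 0.1 at the smallest. The procedure was tried on 12661 simulated genes, of which 50 were changed at each of 4 sizes: it recovered 32% at 1.25-fold, 82% at 1.5-fold, 90% at 2-fold and 96% at 4-fold. Of its calls there 2.6% were unchanged genes, and a comparison without any change gave 0 calls. Far fewer genes changed in the simulation than were called in the real comparisons, so these rates may not carry over.

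The alternatives were limma without trend and robust moderation, quantile normalization, no filter, a filter at 5 FPKM, a pseudocount of 0.1, the replicate number as a block, only the groups compared, and leaving out each library in turn. A further 4 were chosen after seeing the data. These were voom on whole reads recovered from FPKM, thinning of those reads to 17.81 M per library, removal of trends with GC content and length, and median centring without the 50 most abundant genes. Reads were recovered for 98.5% of tested genes. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.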

Results

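RNA from mouse T helper 17 (Th17) cells was sequenced in 12 libraries. Naive CD4+ T cells from the spleen of wild-type C57BL/6J mice had been activated through CD3 and CD28 in a medium that drives Th17 differentiation. The cells received vehicle, ILA at 200 uM, GSK805 at 0.5 uM, or both compounds, with 3 biological replicates in each of the 4 groups. ILA is read here as indole-3-lactic acid, a metabolite that gut bacteria make from tryptophan, and GSK805 is a small-molecule inhibitor of the Th17 programme. The labels call the replicates biological and name no animals, so the p-values measure the spread between these samples. Each library held FPKM values for 28807 genes with a symbol and 715 without, and the reads recovered from them came to between 17.84 M and 23.49 M per library. At that depth 1 read in a gene of 1 kb is worth 0.0426 to 0.056 FPKM. Fold changes are ratios of FPKM + 1, which understates the change of genes with low values, and 13511 genes were tested in every comparison.

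ILA lowered Il17a and Il17f and raised Cyp1a1 and Cyp1b1, targets of the aryl hydrocarbon receptor (AhR), which senses tryptophan metabolites. Il17a, which encodes interleukin-17A, was 4.7-fold lower with ILA than with vehicle: 159 ± 11.5 FPKM against 756 ± 107 FPKM (SD, n = 3; log2 fold change -2.23, SE 0.12, limma adjusted p = 6.4e-08). Il17f was 2.23-fold lower, at 279 ± 12.8 FPKM against 624 ± 51.9 FPKM (adjusted p = 1.1e-07). Cyp1b1 and Cyp1a1, which encode cytochrome P450 enzymes, were 12.6-fold and 3.89-fold higher: Cyp1b1 stood at 68 ± 5.05 FPKM against 4.5 ± 0.414 FPKM (adjusted p = 8.8e-11), and Cyp1a1 at 100 ± 9.6 FPKM against 25 ± 1.96 FPKM (adjusted p = 9.2e-09).

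In the genome build GRCm38, Il17a (ENSMUSG00000025929) lies on chromosome 1 from 20730905 to 20734496 and Il17f (ENSMUSG00000041872) on the same chromosome from 20777146 to 20790617. Cyp1a1 (ENSMUSG00000032315) lies on chromosome 9 from 57687928 to 57703824, and Cyp1b1 (ENSMUSG00000024087) on chromosome 17 from 79701537 to 79715061. Il12rb2 overlaps Serbp1 and Tmem176b overlaps Tmem176a on the opposite strand. Foxp3, whose values were low, overlaps 4 annotated genes, 3 of them on the opposite strand, and several other named genes have such overlaps. Whether the libraries kept the strand is not given in the sources used here.

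Among the other Th17 genes, Il23r, the receptor for interleukin-23, was 3.21-fold lower (1.85 ± 0.354 FPKM with ILA, 8.17 ± 1.33 FPKM with vehicle; adjusted p = 1.1e-06). Ccr6, the chemokine receptor of Th17 cells, was 2.02-fold lower, and Il21, a cytokine that sustains them, 3.47-fold lower (adjusted p = 1.6e-05 and 1.2e-08). Il22 was higher, at 6.51 ± 1.8 FPKM against 2.97 ± 1.58 FPKM (n = 3, adjusted p = 0.0113), although ILA replicate 3 (4.44 FPKM) lay below vehicle replicate 3 (4.59 FPKM). Maf, which encodes the transcription factor c-Maf, was 3.24-fold higher (adjusted p = 1.2e-08). Of the 21 measured genes of the Th17 list, 9 rose, 11 fell and 1 did not pass, with 9 and 11 adjusted over the list alone. The list was not called by camera (adjusted p = 0.168; fry adjusted p = 4.7e-05).

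T helper cytokines fell as a list: 5 of 22 rose and 14 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00298; adjusted p = 0.269 with an estimated correlation). Ifng, the cytokine of Th1 cells, was 4.11-fold lower, Il3 8.38-fold lower and Tnfsf14, which encodes the ligand LIGHT, 5.12-fold lower (adjusted p = 4.0e-07, 3.2e-06 and 4.7e-09). Ltb and Il16 went the other way, 2.82-fold and 2.62-fold higher (adjusted p = 9.7e-09 and 2.1e-09). Il10, which encodes an anti-inflammatory cytokine, was 1.41-fold lower (adjusted p = 0.0138), with all 3 ILA libraries below all 3 vehicle libraries. Of the 7 measured AhR targets, 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0488; adjusted p = 0.351 with an estimated correlation). Ahr was 1.41-fold higher (adjusted p = 6.8e-04).

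Every gene on the list of the unfolded protein response of the endoplasmic reticulum (ER) except Edem1 fell: 14 of 15, also adjusted over the list alone (mean log2 fold change -1.02; camera adjusted p = 3.5e-11; adjusted p = 0.238 with an estimated correlation). Hspa5, the main ER chaperone BiP, stood at 390 ± 19 FPKM with ILA and 958 ± 24.5 FPKM with vehicle (n = 3). Of 23 genes of the ATF4 and amino acid response, 3 rose and 18 fell, also adjusted over the list alone (camera adjusted p = 2.9e-06; adjusted p = 0.238 with an estimated correlation). Cth, an enzyme of cysteine synthesis, was 5.67-fold lower, and the amino acid transporter Slc7a3 3.42-fold lower (adjusted p = 1.5e-08 and 2.3e-09). T cell activation genes fell, 4 of 27 higher and 19 lower, also adjusted over the list alone (camera adjusted p = 2.9e-06; adjusted p = 0.238 with an estimated correlation). Nr4a3, induced by T cell receptor signals, was 2.22-fold lower and the costimulatory receptor Tnfrsf9 2.09-fold lower, while the inhibitory receptor Lag3 was 2.54-fold higher (adjusted p = 1.1e-07, 5.7e-08 and 4.7e-08).

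The largest rises besides Cyp1b1 were Asb2 (11.5-fold), the immune GTPase Gimap4 (7.97-fold), the transcription factor Npas4 (7.46-fold), the T cell adaptor Fyb (5.5-fold) and the interleukin-12 receptor gene Il12rb2 (5.35-fold), with adjusted p between 4.9e-10 and 4.7e-09. Besides Il3 and Cth, the largest falls were those of the repressor Zbtb32 (6.92-fold), the chemokine Xcl1 (6.66-fold) and the microRNA genes Mir7655 (9.71-fold) and Mir23b (5.87-fold). Both microRNA genes are under 200 bp long and hold at most 25 and 19 reads in a library, and Mir7655 lies within Mllt10. The rule that picked these genes required all 3 libraries of one group to lie above all 3 of the other.

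Camera, which sets a list against the other genes, called no other list in this comparison. Fry, which tests a list against no change, passed several that camera did not, among them Treg genes (fry adjusted p = 1.1e-07) and heat shock genes (3.1e-08). Cholesterol synthesis had 14 of 22 genes higher and 2 lower (adjusted p = 0.0993), with Srebf2, a regulator of the pathway, 1.57-fold higher. Glycolysis and hypoxia had 14 of 27 higher and 8 lower (adjusted p = 0.821), among them Gpi1, 1.73-fold higher, and Pgk1, 1.49-fold lower. Treg genes had 8 of 11 higher and 2 lower (adjusted p = 0.0706), type I interferon response 8 of 12 higher and 1 lower (0.101), and Th1 genes 7 of 11 higher and 4 lower (0.339). Cell cycle genes had 9 of 30 higher and 6 lower (0.904), oxidative phosphorylation 3 of 26 higher and 6 lower (0.339), and Tfh genes 4 of 8 higher and 3 lower (0.986). Th2 genes had 2 of 6 higher and 0 lower (0.6), fatty acid synthesis 6 of 11 higher and 4 lower (0.868), and NRF2 oxidative stress 3 of 14 higher and 6 lower (0.339). The counts of these 11 lists were the same adjusted over the list alone, save glycolysis with 15 higher. Naive and quiescent T cell genes had 6 of 12 higher, 7 adjusted over the list alone, and 3 lower (0.448). Heat shock genes had 4 of 12 higher and 7 lower (0.147), circadian clock genes 6 of 15 higher and 6 lower (0.6), and apoptosis and p53 genes 8 of 18 higher and 5 lower (0.986), also adjusted over the list alone. In these last 3 lists the median and the mean differ in sign: -0.18 and 0.04 for heat shock, 0.01 and -0.03 for the clock, and 0.17 and -0.01 for apoptosis, where camera gave Down, Down and Up.

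Across all genes ILA moved 7818 of 13511 (57.9%), 4582 higher and 3236 lower, of which 712 and 228 changed at least 2-fold. In 62.8% of the genes the groups did not overlap, against 10% by chance. Of the calls 58.6% were higher, against 46.3% after quantile normalization, 46.2% with GC and length trends removed and 49.7% with each library centred on its median gene. Foxp3, the regulatory T cell factor, was called at 1.68 ± 0.173 FPKM against 1.23 ± 0.306 FPKM (n = 3, adjusted p = 0.0368), a call lost without vehicle replicate 1 or 3 (0.119 and 0.126), without ILA replicate 1 or 2 (0.125 and 0.0517), with no filter (0.0668), with only the groups compared (0.116), after quantile normalization (0.465), with GC and length trends removed (0.443) and with median centring (0.102). Its alternatives ran from 0.00373 to 0.465. The Il10 call was lost without ILA replicate 3 (0.0568; alternatives from 0.00229).

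**Figure D1:**
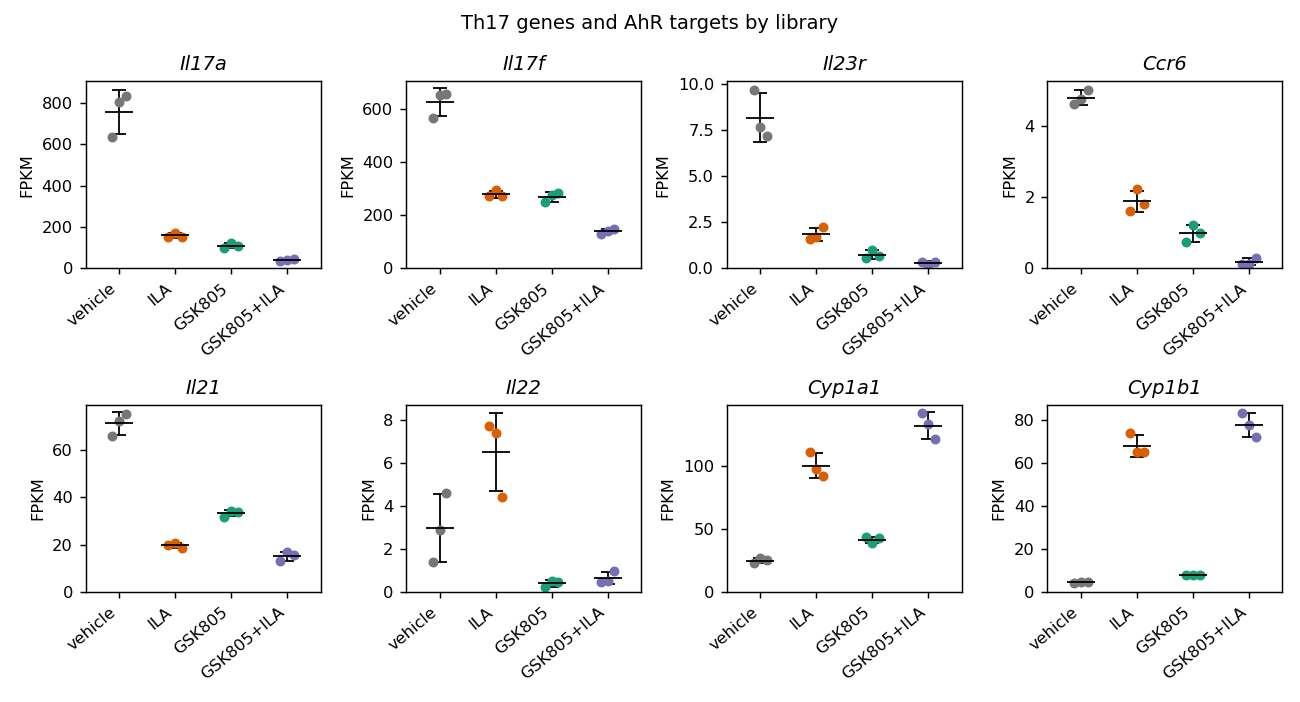
FPKM (vertical axis, starting at 0) of Il17a, Il17f, Il23r, Ccr6, Il21, Il22, Cyp1a1 and Cyp1b1 in the 4 groups, with 1 dot per library and bars for the mean ± SD of 3 libraries. Il17a stands at 756 FPKM with vehicle, 159 with ILA, 109 with GSK805 and 40.1 with both, whereas Cyp1b1 stands at 4.5, 68, 8.05 and 77.7.

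GSK805 alone lowered most measured Th17 genes. Il17a fell 6.87-fold to 109 ± 12.2 FPKM (n = 3; log2 fold change -2.78, SE 0.12, adjusted p = 9.7e-07) and Il23r 5.23-fold to 0.751 ± 0.234 FPKM (adjusted p = 3.2e-06). Ccr6 was 2.94-fold, the chemokine Ccl20 3.53-fold, Il22 2.66-fold and Il17f 2.32-fold lower (adjusted p = 1.2e-05, 1.2e-04, 0.00459 and 3.4e-06). Of 21 Th17 genes 1 rose (Maf) and 14 fell, 1 and 15 adjusted over the list alone, and the list was called (camera adjusted p = 6.7e-15) also with an estimated correlation (adjusted p = 0.00443).

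Cytokines fell as a list, 4 of 22 higher and 8 lower, also adjusted over the list alone (camera adjusted p = 8.4e-04; adjusted p = 0.183 with an estimated correlation), with Il21 2.1-fold and Ifng 1.81-fold lower. T cell activation had 3 of 27 genes higher and 9 lower, 3 and 10 adjusted over the list alone (camera adjusted p = 1.8e-04; adjusted p = 0.173 with an estimated correlation). Nr4a2, an orphan nuclear receptor induced by T cell receptor signals, was 2.89-fold, Nr4a3 1.89-fold and the inhibitory receptor Ctla4 1.84-fold lower (adjusted p = 6.3e-06, 1.3e-05 and 8.4e-05). Naive and quiescent T cell genes rose, 7 of 12 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.0284; adjusted p = 0.188 with an estimated correlation).

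The ER unfolded protein response and ATF4 lists fell by small amounts. Of 15 ER unfolded protein response genes 11 fell, also adjusted over the list alone, by 1.23-fold for Manf, 1.25-fold for Hyou1 and 1.32-fold for Creld2 (camera adjusted p = 3.1e-07; adjusted p = 0.168 with an estimated correlation). Of 23 ATF4 genes 10 fell, 16 adjusted over the list alone, among them Atf3 (1.8-fold) and Slc7a3 (1.59-fold) (camera adjusted p = 3.4e-08; adjusted p = 0.157 with an estimated correlation). Glycolysis and hypoxia had 2 of 27 genes higher and 8 lower, also adjusted over the list alone (camera adjusted p = 2.3e-04; adjusted p = 0.173 with an estimated correlation), with Gapdh 1.34-fold and Pgk1 1.25-fold lower.

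Tfh genes fell, 0 of 8 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.0159; adjusted p = 0.125 with an estimated correlation). Circadian clock genes had 1 of 15 higher and 6 lower, 3 and 8 adjusted over the list alone (0.00194; adjusted p = 0.125 with an estimated correlation). Apoptosis and p53 genes had 2 of 18 higher and 4 lower, 3 and 6 adjusted over the list alone (0.0282; adjusted p = 0.125 with an estimated correlation), a call lost after quantile normalization (0.0516). Markers of CD8 T and NK cells, which activated CD4 T cells can also express, had 0 of 6 higher and 3 lower, also adjusted over the list alone (0.00445; adjusted p = 0.125 with an estimated correlation). AhR targets were not called by camera (adjusted p = 0.154; fry adjusted p = 0.00376), and Cyp1a1 was 1.64-fold higher, at 41.5 ± 2.43 FPKM (n = 3, adjusted p = 2.0e-04).

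GSK805 called 3076 genes (22.8%), 2119 higher and 957 lower, and only 16 and 54 of them changed at least 2-fold. The groups did not overlap in 38.7% of genes, against 10% by chance. The largest rises were those of Ms4a4b (2.02-fold), CT030636.2 (1.93-fold), Hivep3 (1.9-fold), Gimap3 (1.85-fold), Gimap4 (1.84-fold) and Lrmp (1.83-fold), and CT030636.2 lies opposite Airn. The short genes Mir7655 and Snord23, 6.12-fold and 4.74-fold lower, hold at most 25 and 29 reads in a library, and both lie in host genes. Ribosomal protein genes took 12.04% of all FPKM with GSK805 and 14.39% with vehicle (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows).

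Of the GSK805 calls 68.9% were higher, against 55.9% after quantile normalization, 44.5% with GC and length trends removed and 50.2% with median centring. Ahr (0.0483), Foxp3 (0.0267) and CT030636.2 (0.0394) were called but lost the call without GSK805 replicate 1, 2 or 3 or vehicle replicate 3, with adjusted p from 0.0654 to 0.156, 0.0516 to 0.0975 and 0.0626 to 0.113. Without vehicle replicate 2, Ahr (0.162) and CT030636.2 (0.131) also lost it, as did Foxp3 without vehicle replicate 1 (0.0778). Quantile normalization (0.159, 0.0659 and 0.0704), no filter (0.113, 0.0551 and 0.0905), only the groups compared (0.0706, 0.0944 and 0.0583) and median centring (0.101, 0.0596 and 0.052) ended the same 3 calls. Removal of GC and length trends ended those of Ahr (0.111) and Foxp3 (0.0832). Their alternatives ran from 0.00812 to 0.162, 0.00574 to 0.0975 and 0.00742 to 0.131. Mir7655 (0.00524) lost its call with a pseudocount of 0.1 (0.0512; alternatives from 0.00264), and Snord23 (0.00966) with only the groups compared (0.0513; alternatives from 9.7e-04). Il10 did not pass (0.204) but did without vehicle replicate 3 (0.0296; alternatives up to 0.533).

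Both compounds together gave the lowest Il17a and Il17f values of the 4 groups. Il17a stood at 40.1 ± 4.75 FPKM, 18.4-fold below vehicle (n = 3; log2 fold change -4.2, SE 0.12, adjusted p = 2.7e-09), and Il17f at 140 ± 8.57 FPKM, 4.42-fold below (adjusted p = 3.8e-09). Il23r was 7.05-fold, Ccr6 4.92-fold, Il21 4.47-fold, Ifng 3.67-fold and Il22 2.27-fold lower (adjusted p = 3.4e-08, 3.8e-08, 5.8e-09, 1.1e-06 and 0.00422). Cyp1b1 and Cyp1a1 were 14.3-fold and 5.1-fold higher, at 77.7 ± 5.49 and 132 ± 10.6 FPKM (n = 3, adjusted p = 5.0e-11 and 5.2e-09). Of 21 Th17 genes 2 rose and 17 fell, also adjusted over the list alone, and the list was called (camera adjusted p = 3.0e-09) also with an estimated correlation (adjusted p = 0.0256).

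Of 30 cell cycle genes, 21 fell and none rose, also adjusted over the list alone (camera adjusted p = 1.3e-07; adjusted p = 0.143 with an estimated correlation). The replication genes Mcm5 and Mcm7 were 2.07-fold and 1.73-fold lower and Pcna 1.32-fold lower (adjusted p = 4.2e-06, 4.4e-07 and 4.0e-06). Of 15 ER unfolded protein response genes 14 fell, also adjusted over the list alone (camera adjusted p = 2.1e-11; adjusted p = 0.143 with an estimated correlation). Of 23 ATF4 genes 1 rose and 19 fell, 1 and 22 adjusted over the list alone, with Cth 5.64-fold lower (camera adjusted p = 4.4e-11; adjusted p = 0.143 with an estimated correlation). Cytokines had 3 of 22 genes higher and 14 lower, 4 and 14 adjusted over the list alone (8.2e-05; adjusted p = 0.182 with an estimated correlation). T cell activation had 3 of 27 higher and 18 lower, also adjusted over the list alone (2.0e-06; adjusted p = 0.159 with an estimated correlation), and glycolysis and hypoxia 5 of 27 higher and 13 lower, 5 and 16 adjusted over the list alone (0.00131; adjusted p = 0.219 with an estimated correlation). AhR targets, 5 of 7 higher and 1 lower (Il22), missed the threshold (camera adjusted p = 0.0531).

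The largest rises besides Cyp1b1 and Cyp1a1 were those of Gimap4 (8.03-fold), Npas4 (6.89-fold), Asb2 (5.52-fold) and Il12rb2 (4.74-fold). Klrc1, an inhibitory receptor of NK and activated T cells, was 5.03-fold lower, next to Il3 (5.5-fold) and the short gene Mir7655 (9.83-fold). In all, 7033 genes were called (52.1%), 4295 higher and 2738 lower, of which 468 and 209 changed at least 2-fold. The groups did not overlap in 59.2% of genes, against 10% by chance.

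Of these calls 61.1% were higher, against 47.8% after quantile normalization, 45.4% with GC and length trends removed and 49.4% with median centring. Il10 did not pass (log2 fold change -0.07, adjusted p = 0.707) and stood at 0.1 without vehicle replicate 3, while Ahr (1.27-fold higher, adjusted p = 0.00718) was lost after quantile normalization (0.122; alternatives from 3.6e-04) and Foxp3 was 1.43-fold higher (adjusted p = 0.00114).

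ILA added to GSK805, set against GSK805 alone, asks what ILA does when GSK805 is already present. Il17a fell a further 2.67-fold, from 109 ± 12.2 to 40.1 ± 4.75 FPKM (n = 3; log2 fold change -1.42, SE 0.12, adjusted p = 6.1e-06), and Il17f 1.91-fold, from 269 ± 18 to 140 ± 8.57 FPKM (adjusted p = 2.3e-06). Il21 was 2.13-fold, Ifng 2.03-fold, Ccr6 1.68-fold and Irf4, a transcription factor of activated T cells, 1.62-fold lower (adjusted p = 1.8e-06, 2.3e-04, 3.7e-04 and 1.6e-06). Ccr6 lay near the floor, at 0.755 to 1.21 FPKM with GSK805 and 0.116 to 0.294 FPKM with both, so its fold of FPKM + 1 is understated. Cyp1b1 was 8.68-fold, Asb2 8.48-fold and Cyp1a1 3.12-fold higher (adjusted p = 9.9e-10, 5.4e-09 and 1.9e-07). Il22 (adjusted p = 0.549), Ahr (0.571) and Foxp3 (0.224) did not pass.

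Th17 genes fell as a list, 4 of 21 higher and 10 lower, also adjusted over the list alone (camera adjusted p = 0.034; adjusted p = 0.27 with an estimated correlation), and quantile normalization ended the call (0.0641). Of 30 cell cycle genes 22 fell and none rose, with 1 higher and 22 lower adjusted over the list alone (camera adjusted p = 3.6e-09; adjusted p = 0.162 with an estimated correlation). Mcm5 was 1.88-fold and Pcna 1.29-fold lower. ER unfolded protein response genes fell in 13 of 15 cases, also adjusted over the list alone (mean log2 fold change -0.58; 8.0e-11; adjusted p = 0.162 with an estimated correlation). Of 23 ATF4 genes 1 rose and 18 fell, 2 and 19 adjusted over the list alone, with Cth 3.41-fold and Sesn2 1.41-fold lower (2.0e-08; adjusted p = 0.186 with an estimated correlation). Cytokines had 3 of 22 higher and 10 lower, also adjusted over the list alone (0.00402; adjusted p = 0.287 with an estimated correlation). T cell activation had 4 of 27 higher and 14 lower, 7 and 15 adjusted over the list alone (0.00824; adjusted p = 0.383 with an estimated correlation).

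Treg genes rose as a list, 7 of 11 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.00857; adjusted p = 0.162 with an estimated correlation), with Ctla4 2.24-fold higher. AhR targets rose, 3 of 7 higher and 0 lower, also adjusted over the list alone (0.00824; adjusted p = 0.27 with an estimated correlation). Type I interferon response genes rose, 8 of 12 higher, 9 adjusted over the list alone, and 1 lower (0.0369; adjusted p = 0.186 with an estimated correlation). The largest changes besides those named were the rises of Npas4 (5.26-fold), Gimap4 (4.37-fold), Il12rb2 (4.36-fold) and Hic1 (4.12-fold), and the falls of the short gene Mir3074-2 (4.15-fold), Il3 (3.84-fold), Mcpt1 (3.78-fold), Zbtb32 (3.6-fold) and Mcpt2 (3.33-fold). Mir3074-2 is 83 bp long, holds at most 22 reads in a library and lies opposite Mir24-2. Mcpt1 and Mcpt2 encode related mast cell proteases and can share reads.

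In total 5331 genes were called (39.5%), 2968 higher and 2363 lower, with 183 and 87 changed at least 2-fold, and 52.1% of genes did not overlap between the groups, against 10% by chance. Of these calls 55.7% were higher, against 46.8% after quantile normalization, 46.5% with GC and length trends removed and 50.4% with median centring. The Il23r call (1.35-fold lower, adjusted p = 0.0271) was lost without GSK805 replicate 2 (0.105) and without GSK805+ILA replicate 2 (0.0927) and with no filter (0.0651), over alternatives from 0.00479. Its values were also near the floor, at 0.584 to 1.02 FPKM with GSK805 and 0.179 to 0.359 FPKM with both, so this fold is understated too. Il10 did not pass (0.0795) but did after quantile normalization (0.0361) and with only the groups compared (0.0178), over alternatives up to 0.206.

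GSK805 added to ILA, set against ILA alone, asks what GSK805 does when ILA is present. Il17a was 3.91-fold lower, at 40.1 ± 4.75 FPKM against 159 ± 11.5 FPKM (n = 3; log2 fold change -1.97, SE 0.12, adjusted p = 1.3e-05), and Il22 4.45-fold lower, at 0.668 ± 0.286 FPKM against 6.51 ± 1.8 FPKM (adjusted p = 5.8e-04). Ccl20 was 3.2-fold, Tmem176b, an ion channel gene typical of Th17 cells, 2.43-fold and Il17f 1.98-fold lower (adjusted p = 2.7e-04, 2.9e-06 and 2.0e-05). Of 21 Th17 genes 1 rose (Irf4) and 17 fell, also adjusted over the list alone, and the list was called (camera adjusted p = 7.6e-16) also with an estimated correlation (adjusted p = 0.00382).

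Further lists fell and held with an estimated correlation. Of 30 cell cycle genes 24 fell and none rose, 27 adjusted over the list alone (camera adjusted p = 8.2e-17; adjusted p = 0.0203 with an estimated correlation). The proliferation marker Mki67 went from 19.3 ± 0.636 FPKM with ILA to 11 ± 0.668 FPKM with both (n = 3; 1.7-fold, adjusted p = 3.1e-05), and the topoisomerase Top2a fell 1.47-fold. Of 27 glycolysis and hypoxia genes 16 fell and none rose, also adjusted over the list alone (8.2e-11; adjusted p = 0.0374 with an estimated correlation), with Tpi1 1.35-fold, Ldha 1.31-fold and Eno1 1.29-fold lower. Of 22 cholesterol synthesis genes 9 fell and none rose, also adjusted over the list alone (5.1e-05; adjusted p = 0.0154 with an estimated correlation), with Stard4 1.57-fold and Srebf2 1.25-fold lower.

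ER unfolded protein response genes rose, 13 of 15 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 8.8e-08; adjusted p = 0.175 with an estimated correlation). Hspa5 went from 390 ± 19 to 554 ± 14.5 FPKM (n = 3; 1.42-fold, adjusted p = 7.0e-05). ATF4 genes had 1 of 23 higher and 7 lower, 2 and 7 adjusted over the list alone (0.0236; adjusted p = 0.479 with an estimated correlation), and NRF2 genes 4 of 14 higher and 0 lower, 5 and 2 adjusted over the list alone (0.0363; adjusted p = 0.464 with an estimated correlation). Th1 genes had 2 of 11 higher and 4 lower, 2 and 5 adjusted over the list alone (0.0256; adjusted p = 0.193 with an estimated correlation), and Tfh genes 0 of 8 higher and 2 lower, 0 and 4 adjusted over the list alone (0.0363; adjusted p = 0.174 with an estimated correlation). Clock genes had 2 of 15 higher and 6 lower, 2 and 7 adjusted over the list alone (0.0431; adjusted p = 0.193 with an estimated correlation). B cell markers had 0 of 5 higher and 3 lower (Cd79a, Cd74, H2-Ab1), also adjusted over the list alone (0.0256; adjusted p = 0.214 with an estimated correlation). T cell activation genes went both ways, 12 of 27 higher and 7 lower, 14 and 8 adjusted over the list alone, without a camera call (0.192; fry adjusted p = 0.0331), with Tnfrsf9 1.51-fold, Egr2 1.5-fold and Cd69 1.49-fold higher.

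The largest falls besides Il22, Il17a and Ccl20 were those of the interferon-induced Ifitm1 (3.59-fold), Olfr60 (3.51-fold) and Tent5a (2.59-fold). The largest rises were those of Tnfsf14 (2.19-fold), Klf2, a factor of quiescent T cells, and Oaf (both 1.9-fold), Tnfsf4, which encodes OX40 ligand (1.74-fold), and the small nucleolar RNA genes Snord49b (2.39-fold) and Snora73b (1.85-fold). In total 2507 genes were called (18.6%), 1340 higher and 1167 lower, with 13 and 50 changed at least 2-fold, and 37.2% of genes did not overlap between the groups, against 10% by chance. The count fell to 1596 without GSK805+ILA replicate 3. Snora73b (adjusted p = 0.0281) and Snord49b (0.0329) lost the call without ILA replicate 2 (0.0829 and 0.0702) or GSK805+ILA replicate 3 (0.101 and 0.105), Snora73b also without GSK805+ILA replicate 1 (0.0869) and Snord49b without replicate 2 (0.0812). No filter (0.0654 and 0.0763) and only the groups compared (0.0502 and 0.0623) also ended both calls, over alternatives from 0.00821 and 0.0241. No filter ended the calls of Th1 genes (0.0971) and B cell markers (0.0828).

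**Figure D2:**
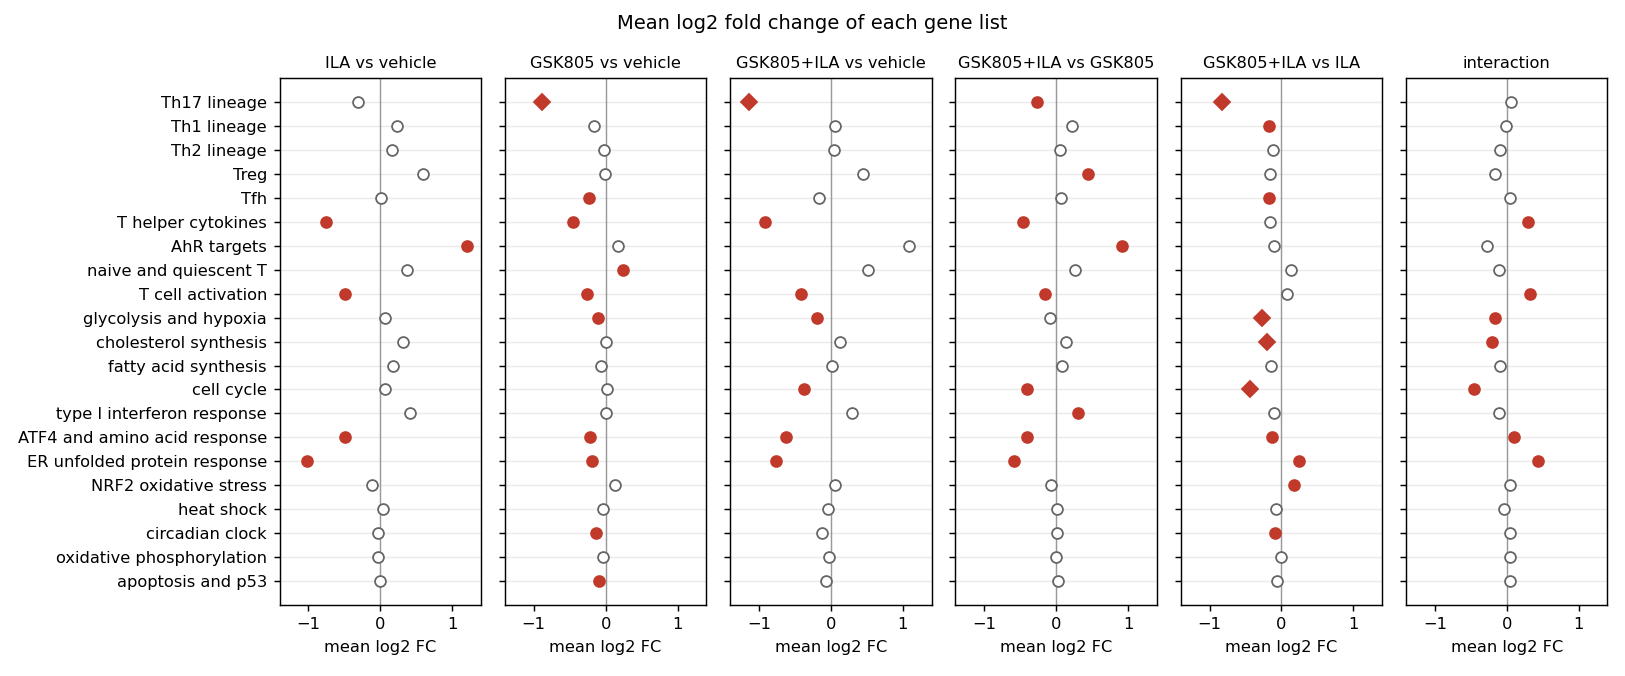
Mean log2 fold change (horizontal axis) of the 21 T cell and pathway lists in the 6 comparisons, with red circles for lists called with the preset correlation, red diamonds for those also called with an estimated correlation, and open grey circles for lists not called. The Th17 list is called both ways in 3 comparisons, with means of -0.89 for GSK805 against vehicle, -1.14 for both against vehicle and -0.83 for both against ILA.

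The interaction asks whether the effect of ILA differs with and without GSK805, and a positive value means that ILA raised the gene more, or lowered it less, when GSK805 was present. ER unfolded protein response genes fell less with ILA when GSK805 was present: 13 of 15 were higher in the interaction, 14 adjusted over the list alone (mean log2 difference 0.44; camera adjusted p = 2.9e-14; adjusted p = 0.129 with an estimated correlation). Hspa5 (ENSMUSG00000026864, chromosome 2 from 34771970 to 34777547) fell from 958 ± 24.5 to 390 ± 19 FPKM without GSK805 and from 851 ± 45.1 to 554 ± 14.5 FPKM with it (n = 3; difference 0.68, SE 0.07, adjusted p = 4.3e-04). Mki67 (ENSMUSG00000031004, chromosome 7 from 135689784 to 135716361) went from 14 ± 1.04 to 19.3 ± 0.636 FPKM with ILA alone and from 15.8 ± 0.498 to 11 ± 0.668 FPKM with ILA on top of GSK805 (n = 3; difference -0.93, SE 0.08, adjusted p = 4.3e-04). Of 30 cell cycle genes 17 were lower in the interaction and none higher, 22 adjusted over the list alone (mean -0.46; camera adjusted p = 3.9e-10; adjusted p = 0.129 with an estimated correlation).

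T cell activation genes were higher in the interaction, 12 of 27 and none lower, 14 adjusted over the list alone (camera adjusted p = 7.5e-09; adjusted p = 0.129 with an estimated correlation), with Nr4a2 at 1.03 and Tnfrsf9 at 0.72 (log2 differences; adjusted p = 0.00161 and 8.7e-04). Cytokines had 6 of 22 higher and 3 lower, 7 and 3 adjusted over the list alone (0.0257; adjusted p = 0.486 with an estimated correlation). Tnfsf14 stood at 1.27 and Ltb at -0.6 (adjusted p = 4.3e-04 and 0.00267). Glycolysis and hypoxia had 9 of 27 lower and none higher, 2 higher and 10 lower adjusted over the list alone (0.031; adjusted p = 0.486 with an estimated correlation), and cholesterol synthesis 3 of 22 lower and none higher, 0 and 5 adjusted over the list alone (0.0407; adjusted p = 0.151 with an estimated correlation). ATF4 genes had 6 of 23 higher and 2 lower, also adjusted over the list alone (0.031; adjusted p = 0.553 with an estimated correlation), and CD8 T and NK markers 1 of 6 higher and 1 lower, 4 and 1 adjusted over the list alone (0.0407; adjusted p = 0.255 with an estimated correlation). After quantile normalization cytokines (0.075), cholesterol synthesis (0.0692), ATF4 genes (0.58) and CD8 T and NK markers (0.075) were no longer called, and fry, which tests against no change, did not pass cytokines (0.0871) and ATF4 genes (0.153).

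The other large interactions were Xcl1 (1.42), Il23r (1.25), the ectonucleotidase Nt5e (-0.95), Rab29 (-0.97), Hivep3 (-1.01) and Ifitm1 (-1.33), together with the short genes Rnu12 (2.2), Mir7655 (2.6), Mir23b (2) and Mir135a-1 (-1.44), which hold at most 25 reads in a library. Genes named for other comparisons gave 0.81 for Il17a and 1.02 for Ifng (adjusted p = 0.0117 and 0.00993), while Il17f (0.22), Il22 (-0.74), Ahr (-0.42) and Cyp1a1 (-0.32) did not pass (0.159, 0.242, 0.0516 and 0.0946). Cyp1b1 (-0.53) passed (adjusted p = 0.00654), as did Gimap4 (-0.87, adjusted p = 9.3e-04). In total 1871 genes passed (13.8%), 696 positive and 1175 negative. In 1527 of them the effect of ILA was smaller in size with GSK805 present, in 39 it was larger, and in 305 it had the opposite sign. The effect with GSK805 present is measured from GSK805 alone, so a start already moved by GSK805 can also make it smaller.

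Of the interaction calls 37.2% were positive, against 46% after quantile normalization, 57.6% with GC and length trends removed and 52.5% with median centring, and the count fell to 1229 without vehicle replicate 3, 1206 without GSK805 replicate 1, 1195 without GSK805+ILA replicate 3 and 1067 with no filter on low genes. The Il23r call (0.00282) was lost with a pseudocount of 0.1 (0.0923) and with voom on recovered reads (0.246; alternatives from 0.00224), Ifitm1 (0.0203) without GSK805 replicate 1 (0.0509) and with no filter (0.0566; alternatives from 0.0038), and Pfkl (0.0111) with GC and length trends removed (0.0541; alternatives from 3.6e-04). Mir135a-1 (0.0462) lost the call without any one library other than ILA replicate 3 and GSK805 replicate 3 (0.06 to 0.0901), Mir23b (0.0419) without any one other than ILA replicate 1, GSK805 replicate 1 and GSK805+ILA replicate 3 (0.0506 to 0.089), and Mir7655 (0.0413) without any one other than vehicle replicates 1 and 2, ILA replicate 1 and GSK805 replicate 1 (0.0583 to 0.0949). Over all alternatives these ran from 0.0256 to 0.142, 0.0301 to 0.0973 and 0.0194 to 0.187.

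**Figure D3:**
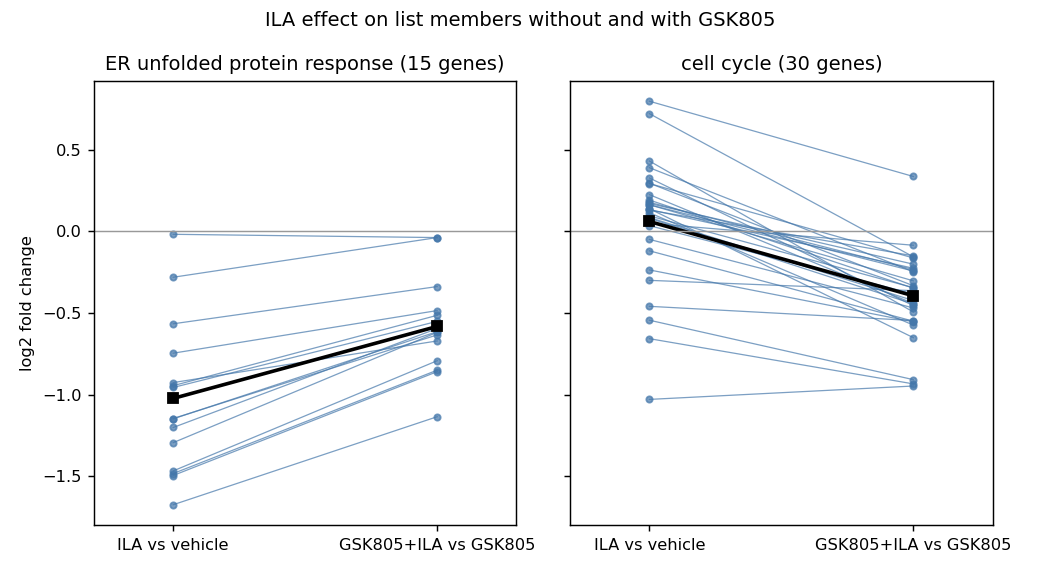
Log2 fold change (vertical axis) of the 15 ER unfolded protein response genes and 30 cell cycle genes, each line linking a gene's value for ILA against vehicle with its value for both compounds against GSK805, and black squares marking the mean. The mean goes from -1.02 to -0.58 for the ER genes and from 0.06 to -0.4 for the cell cycle genes.

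The effects of ILA with and without GSK805 share no library and can be set against each other directly. Across the 13511 genes, which are not independent replicates, the log2 fold changes correlated (Pearson r 0.787, Spearman rho 0.774), with a slope of 0.54 for the effect in the presence of GSK805. Both comparisons called 4685 genes, and 99% of these went the same way: 2675 were higher in both (1006.5 by chance) and 1964 lower in both (566 by chance). The effects of GSK805 with and without ILA correlated less (r 0.251, rho 0.191, slope 0.25), and 82.8% of 906 genes called in both went the same way. The GSK805 effects were smaller, with median absolute log2 fold changes among called genes of 0.31 without ILA and 0.3 with it. Those of ILA were 0.46 without GSK805 and 0.36 with it. Noise lowers r and slope more where effects are small, so these values do not measure how far ILA weakens GSK805. ILA and GSK805, each against vehicle, shared 1528 higher genes and 539 lower genes, or 86.1% of 2402, counts to which the shared vehicle libraries contribute. Their correlation (r 0.439, rho 0.465) includes what the shared vehicle libraries contribute: unchanged groups simulated on the same controls gave r 0.497 and a covariance of 0.0122 in 100 draws, against an observed covariance of 0.065. The excess of 0.0529 is what remains once the simulated covariance is taken out. The draws treated genes as independent, so deviations of the vehicle libraries that run across many genes were not simulated. With 3 controls these cannot be parted into separate sets of at least 2, so a part of the excess from such deviations stays open.

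**Figure D4:**
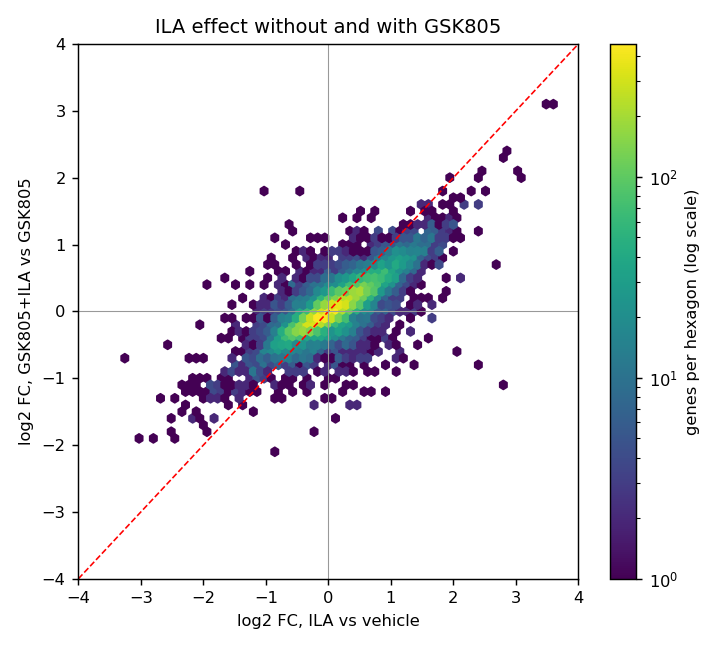
Log2 fold change of ILA against vehicle (horizontal axis) and of both compounds against GSK805 (vertical axis) for 13511 genes, coloured on a log scale by the number of genes per hexagon, with the red dashed line marking equal values. The cloud is flatter than that line, with a slope of 0.54 and r 0.787.

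Markers of other cells were present at varied levels. On the CD8 T and NK list, Klrc1 and Klrd1 stood at 52.6 and 15.3 FPKM with vehicle. The lists of erythroid and platelet markers (1 of 5 higher, Car2, and 1 lower, Itga2b), B cell markers (1 of 5 higher and 1 lower; median 0.11, mean 0, camera Down) and CD8 T and NK markers (1 of 6 higher and 5 lower) were not called for ILA against vehicle (camera adjusted p = 0.515, 0.986 and 0.0706), with the same counts adjusted over the list alone. Lists with fewer than 5 measured members were not tested. Among them, Ctss, a protease of antigen-presenting cells, stood at 34.3 ± 3.45 FPKM with vehicle and 67.2 ± 6.95 FPKM with ILA, while Cd68 stood at 3.75 ± 0.768 and 8.94 ± 0.431 FPKM and Csf1r at 3.46 ± 0.334 and 2.33 ± 0.487 FPKM (n = 3). For gamma delta T cells, Tcrg-C2 stood at 1.1 ± 0.37 FPKM with vehicle and 0.148 ± 0.145 FPKM with ILA, and for stromal cells Lum stood at 5.88 ± 0.699 and 3.74 ± 0.415 FPKM and Pecam1 at 4.44 ± 0.315 and 10.6 ± 0.637 FPKM. Haemoglobin genes exceeded 1 read in ILA replicate 2 alone, with Hba-a1 at 18.2 FPKM and Hbb-bs at 23.3 FPKM, and without that library ILA against vehicle called 7157 genes.

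Libraries of a group correlated at 0.983 to 0.987 across genes and libraries of different groups at 0.94 to 0.981. No pair of libraries held identical values. Abundant pseudogenes with Gm symbols took 7.19% of all FPKM with vehicle, 7.98% with ILA, 6.86% with GSK805 and 8.45% with both. The difference of ILA and of both from vehicle had the smallest exact permutation p of 0.1 (two-sided). Whether reads given to these pseudogenes arise from other genes was not tested. The 50 most abundant genes took 22.31% with vehicle and 20.11% with GSK805 (exact permutation p = 0.1). Reads in genes averaged 19.42 M with ILA and 21.1 M with vehicle.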

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

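The effect of ILA differed with and without GSK805 in 1871 genes. The tests of 2 of the patterns in this part, on ER unfolded protein response genes and on cell cycle genes, were chosen after the results were seen. In 100 regroupings of the 12 libraries, only 1, the true one, called as many genes, and the highest other gave 193. Regrouping mixes libraries of groups that differ in many genes, which by itself lowers such counts, so it says little about chance in the interaction. For the pairwise comparisons the true grouping was 1 of 10 splits each for ILA, GSK805 and both against vehicle, and for both against GSK805 and against ILA. The highest other split gave 0, 1, 1, 0 and 0 genes, and 10 splits are too few for a share under 0.05.

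Lists that differed were ER unfolded protein response (camera adjusted p = 2.9e-14), cell cycle (3.9e-10), T cell activation (7.5e-09), T helper cytokines (0.0257), glycolysis and hypoxia (0.031), ATF4 and amino acid response (0.031), cholesterol synthesis (0.0407) and CD8 T and NK markers (0.0407). None of the 8 held with an estimated correlation, where adjusted p ran from 0.129 to 0.553. Log2 differences above 0 among genes that passed included those of Mir7655 (2.6), Rnu12 (2.2), Mir23b (2), Xcl1 (1.42), Tnfsf14 (1.27), Il23r (1.25), Nr4a2 (1.03), Ifng (1.02), Il17a (0.81), Cth (0.74), Tnfrsf9 (0.72), Hspa5 (0.68), Nr4a3 (0.68), Manf (0.67), Slc7a3 (0.55), Hsp90b1 (0.53) and Psat1 (0.32). Those below 0 included Mir135a-1 (-1.44), Ifitm1 (-1.33), Hivep3 (-1.01), Rab29 (-0.97), Nt5e (-0.95), Mki67 (-0.93), Top2a (-0.69), Il16 (-0.64), Ccna2 (-0.63), Ltb (-0.6), Ldha (-0.35), Pfkl (-0.34) and Eno1 (-0.3).

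ER unfolded protein response genes fell less with ILA when GSK805 was present, by a mean log2 difference of 0.44. Thinning all libraries to equal depth gave 0.44 (SE 0.05) and removal of GC and length trends 0.48 (SE 0.06). Median centring without the 50 most abundant genes gave 0.47 (SE 0.06). In that order, these steps moved the interaction of genes by a median of 0.016, 0.042 and 0.045. The list kept its difference, so GC and length trends and a shift common to all genes, as removed here, do not account for it. Thinning hardly changes expected FPKM, so it cannot decide whether depth plays a part. Across genes the effect of ILA tended to be smaller with GSK805, with a slope of 0.54, so a general weakening may be enough. The weakening was not uniform: among genes that passed the interaction, the effect was smaller in 1527, larger in 39 and opposite in sign in 305. A smaller effect need not mean a lower level with both compounds. Gimap4 reached 213 to 240 FPKM with ILA and 225 to 237 FPKM with both. It started from 26 to 30.9 FPKM with vehicle and a higher 49 to 56.7 FPKM with GSK805. Asb2 went the other way, at 54.7 to 60.1 FPKM with ILA and 25.8 to 29.6 FPKM with both. How the genes divide between these courses was not counted. Whether the groups were grown or sequenced in separate batches is not given in the labels, and that explanation stays open.

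Cell cycle genes took a different course: a mean log2 fold change of 0.06 for ILA alone and -0.4 for ILA on top of GSK805, an interaction of -0.46. It was -0.45 (SE 0.05) after thinning, -0.41 (SE 0.06) without GC and length trends and -0.41 (SE 0.06) with median centring. A general weakening of the ILA effect alone would shrink the list mean and keep its sign, whereas the mean went from 0.06 to -0.4. The mean for ILA alone covers members that went both ways, so it does not measure how far single genes moved. Some members, such as Mki67, turned from a rise to a fall. Its biological cause was not tested, and cell numbers were not analysed here. Separate culture batches stay open here too.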

How the results depend on the processing

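Counts of called genes moved more than 1.5-fold in few alternatives. The interaction fell from 1871 to 1067 with no filter on low genes, where more genes share the adjustment. Leaving out 1 library gave 1195 (without GSK805+ILA replicate 3) to 1969 (without vehicle replicate 1) for the interaction, with 1206 without GSK805 replicate 1 and 1229 without vehicle replicate 3. For both compounds against ILA it gave 1596 (without GSK805+ILA replicate 3) to 2160 (without ILA replicate 3). The other ranges were 7114 to 7384 for ILA and 2098 to 2998 for GSK805 against vehicle, 6304 to 6667 for both against vehicle, and 4423 to 4857 for both against GSK805. Fewer libraries give less power.

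The replicate block took the replicate number as a paired factor. It called 7793, 3081, 7066, 5343, 2513 and 1975 genes in the 6 comparisons, ended the calls of Foxp3 with ILA (0.0544), Snord49b (0.0582) and Mir135a-1 (0.0702) and of AhR targets with ILA (0.0565), and gave correlations of 0.439, 0.787 and 0.251 for effect sharing. The labels do not say whether the numbers pair the samples. Over 18 pairs of libraries with the same number, deviations from the group mean correlated at -0.082 to 0.078. Their mean was 0.01, against -0.005 for pairs with different numbers, and 6 of 12 libraries correlated best with one of their own number. With 3 libraries per group these values show no strong pairing but cannot exclude it.

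The sign turned only for genes that did not pass. Il10 with both against vehicle (-0.07) ran from -0.22 without vehicle replicate 1 to 0.1 without vehicle replicate 3. Ahr with both against GSK805 (0.07) was -0.02 after quantile normalization. The cause was not tested.

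Effect sharing among genes called in either comparison was 0.484 for ILA and GSK805, 0.863 for ILA with and without GSK805 and 0.375 for GSK805 with and without ILA. It ran from 0.395 (without GSK805 replicate 1) to 0.475 (without vehicle replicate 1), 0.757 (without GSK805 replicate 3) to 0.783 (without vehicle replicate 2), and 0.221 (without GSK805 replicate 3) to 0.256 (without GSK805+ILA replicate 3). A higher correlation among called genes follows from their selection. Of 51 camera calls, 6 held with an estimated correlation and 45 were lost, and 45 held after quantile normalization. Fry, which asks whether a list changed at all and not whether it changed more than other genes, passed 49 of the same lists.

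Voom on recovered reads called 7989, 3702, 7361, 5922, 3124 and 2636 genes, thinning 7728, 2956, 7014, 5263, 2474 and 1817, removal of GC and length trends 7889, 2704, 7218, 5562, 2629 and 1997, and median centring 7741, 2644, 7119, 5383, 2419 and 1857. These 4 were chosen after the data were seen.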

Other observations

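The genes in this and the next paragraph were chosen after their values were seen. Genes of the Th1 list went both ways under ILA. Il18r1, a subunit of the interleukin-18 receptor, went from 5.25 ± 0.411 to 24 ± 0.774 FPKM (n = 3, limma adjusted p = 2.3e-09), and Il18rap, its partner, from 2.1 ± 0.276 to 9.45 ± 0.192 FPKM (adjusted p = 4.7e-08). The transcription factor Runx3 went from 6.27 ± 0.655 to 17.9 ± 0.57 FPKM (adjusted p = 5.9e-08). The chemokine receptor Cxcr3 fell from 4.53 ± 0.336 to 0.234 ± 0.101 FPKM and the chemokine Ccl5 from 11.8 ± 1.9 to 2.79 ± 0.566 FPKM (adjusted p = 5.4e-07 and 3.5e-07). With GSK805 present, Il18r1 went from 5.23 ± 0.51 to 12.7 ± 0.496 FPKM, a smaller rise (interaction -0.86, adjusted p = 8.3e-04).

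Genes of naive and quiescent T cells also split. Tcf7 and Lef1, transcription factors of naive and memory cells, rose with ILA, Tcf7 from 140 ± 3.2 to 336 ± 8.85 FPKM and Lef1 from 4.6 ± 0.566 to 14.7 ± 0.538 FPKM (n = 3, adjusted p = 2.9e-09 and 2.5e-08). Bach2, a repressor that keeps T cells quiescent, fell from 102 ± 5.8 to 70.4 ± 2.61 FPKM (adjusted p = 1.4e-06). Among heat shock genes, Hspa1a and Hspa1b, near-identical copies that can share reads, went from 2.57 ± 0.625 to 9.69 ± 1.81 and from 4.06 ± 0.537 to 15.6 ± 1.97 FPKM, while Hsp90aa1 fell from 246 ± 3.14 to 131 ± 1.16 FPKM (adjusted p = 1.5e-05, 1.0e-05 and 1.1e-09).

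Genes of the T cell itself were higher with ILA, a pattern noticed in the data. Cd4 went from 42.4 ± 1.18 to 117 ± 5.29 FPKM, Cd3e from 19 ± 0.313 to 37.5 ± 0.768 FPKM and Trac from 189 ± 7.75 to 309 ± 16 FPKM (n = 3; 2.71-fold, 1.92-fold and 1.63-fold; adjusted p = 1.6e-09, 1.6e-08 and 5.6e-07). Their mean log2 fold change of 1.03 was 1.03 (SE 0.02) after thinning and 0.98 (SE 0.03) without GC and length trends. A lower share of T cells in the vehicle cultures could raise all T cell genes, and the test set beforehand went with it, though narrowly. Of 23 other T cell genes 20 were higher, 1 was lower (Fyn) and 2 did not pass. Their median log2 fold change of 0.55 only just reached the limit of that test, set from the mean of the 3 genes. The rise was uneven, with quartiles of 0.31 and 1.03.

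A further test was chosen after that result was seen. In it, 50 markers of B, myeloid, erythroid, platelet and stromal cells had a median of 0.0928 FPKM in vehicle, with 12 at 1 FPKM or more and 2 at 10 or more (Ctss, Car2). Most of these markers were thus near the floor, but a median pooled over several cell types would stay low if a single type were present. The test therefore cannot exclude that such a type makes up a missing share. A lower share of T cells without ILA may still be the cause in whole or in part: dying cells and cells without markers on these lists were not tested. CD8 T and NK markers were left out of this test, though the cultures began from isolated naive CD4+ T cells. Most tested markers of that list were lower with ILA than with vehicle, but the list was not called, and activated CD4 T cells can also express them. A change within the T cells stays open as well.

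Haemoglobin transcripts in ILA replicate 2, with 278 reads of Hba-a1 and 336 of Hbb-bs against 0 or 1 in every other library, were also noticed in the data. Leaving that library out gave 7157 calls for ILA against vehicle, so a trace of red cells in that library is not likely to drive the comparison. The share of abundant pseudogenes, a set picked from the data, was higher with ILA (7.98% and 7.19%, exact permutation p = 0.1), and its cause was not tested.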
